A study of Mus musculus with 12 samples.

How the data were processed

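RNA was measured in the prefrontal cortex of C57BL/6 mice in a design that crossed diet (control or high fructose) with stress (unstressed or stressed), with 3 samples in each group and 12 samples in all. The kind and length of the stress, the composition and duration of the diets, the age of the mice and the time of day of collection were not given in the sources used here. Per the labels' protocols, total RNA was treated with DNase I, ribosomal RNA was depleted, and paired-end libraries were read on an MGI nanoball sequencer. Depletion of ribosomal RNA, in place of selection of poly(A) tails, leaves noncoding and unspliced transcripts in the libraries.

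The deposited values were whole-number counts of fragments per gene, in 1 table of 55487 genes, made by the authors before deposit. Per the file headers, the authors counted with featureCounts 2.0.1 in paired mode on the Ensembl GRCm38 annotation, release 100. The strand option was 0, and neither multi-mapping fragments nor fragments overlapping more than 1 gene were counted. Per the submitters' processing notes, reads were checked with FastQC, trimmed with cutadapt and aligned with HISAT2 to mm10, and DESeq2 was named without its design. Because the counting did not use strand, fragments of a gene and of a partner on the opposite strand could not be told apart. Of the 300 genes that could be named in the text, 95 shared exon sequence with another gene, 79 of them with a gene on the opposite strand, so their values are uncertain to that extent. Leaving out multi-mapping fragments lowers the counts of repeated sequences and near-identical copies.

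Total counts per sample ran from 25.1 to 36.1 M fragments, so depth differed little between groups. The genes tested held 99.88% to 99.92% of them. Symbols were matched to 55141 of the gene identifiers, and 346 had none. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom from 3.67 to 10.1, so no library was counted as a copy of another. The labels name separate samples without saying that each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical. The common biological coefficient of variation was 7.19%.

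Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 22460 genes, library sizes were scaled by TMM, and 1 robust quasi-likelihood model with 4 group means was fitted to all 12 samples. F tests were made for stress on each diet, for high fructose without and with stress, for both together against neither, for stress averaged over diets, for fructose averaged over stress, and for the diet by stress interaction. P-values were adjusted by Benjamini and Hochberg, and an adjusted p under 0.05 was called. A log2 fold change is given with the standard error (SE) implied by its F statistic. Group means are CPM, the counts scaled by the TMM-corrected library size, given with the SD over 3 samples. In the text, an adjusted p without another name is from this edgeR test.

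Before the data were examined, 49 gene lists of pathways, cell types and neighbouring brain regions were written from textbook knowledge, and 48 had at least 5 tested members. Each list was compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated from the data. Where the estimated correlation ended a call, its adjusted p is given. Counts of list members are those passing over all genes tested, and the count adjusted over the list alone is given beside them. Genes were named by a rule written at the same time. Among called genes of at least 1 CPM and with more than a predicted-gene name, it took the 8 largest rises and falls and the 6 smallest p-values in each direction. Without that floor it added called members of the lists, and 18 genes of prior interest whether called or not. Where fewer than 10 genes were called it took all of them and the 10 smallest p-values.

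The steps were tested on simulated data with known changes. For stress on the control diet, with 22079 genes, the test recovered 74 of 100 genes changed 1.5-fold and 94 of 100 changed 2-fold, and 10 of its calls, 5.32%, were false. DESeq2 recovered 79 and 94 of them, with 21 false calls. The simulated genes were drawn independently of each other, without any difference between libraries beyond depth. The real data hold both correlated genes and such differences, so the false share may be higher there. Alternatives set before the data were examined were DESeq2 1.42.0, RLE scaling, no filter on low counts, only the samples of the groups compared, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and leaving out each library in turn. A covariate for olfactory bulb genes and a fit without 3 libraries low in Malat1 were added after the data were seen. No sample was left out, and no column of the table was unmapped.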

Results

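The data are 12 libraries of ribosomal-RNA-depleted total RNA from mouse prefrontal cortex, 3 from each of 4 groups: control diet without stress, control diet with stress, high fructose without stress, and high fructose with stress. The series concerns a fructose-rich diet, metabolic disorder and psychiatric illness, and asks which cortical genes change. Depth was 25.1 to 31.9 M counted fragments in the control unstressed libraries, 25.2 to 34.8 M in control stressed, 28.8 to 36.1 M in fructose unstressed and 29.8 to 31.3 M in fructose stressed. All libraries carried Y-linked transcripts, with Ddx3y at 27 to 34.3 CPM, and little Xist, at most 0.759 CPM. Among the genes named below and in the closing section, Aldoa, Atp5f1, Cebpd, Col4a1, Cyp51, Dlx1, Glyctk, Htr1b, Notch3, Shisa3, Tpi1 and Zic1 share exon sequence with a gene on the opposite strand of at least 1 CPM, as do Gabra4 and Gabrb1 with each other, so their values are uncertain to that extent.

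The control unstressed libraries stood apart from all others. On the first principal component, which held 30.1% of the variance of 2000 genes, these 3 libraries lay at -25.8 to -24.1 and the 9 others at -4 or above. Genes typical of the olfactory bulb were high in them. Eomes, a transcription factor of mitral and tufted neurons (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132, mm10), stood at 9.46 ± 0.78 CPM (SD, n = 3) against 0.101 ± 0.046 in control stressed, 0.0839 ± 0.022 in fructose unstressed and 0.0996 ± 0.12 in fructose stressed. Th, the rate-limiting enzyme of dopamine synthesis, stood at 12.5 ± 1.4 CPM against 1.13 ± 0.42, 1.04 ± 0.14 and 1.18 ± 0.2. Cdhr1, a cadherin of the bulb and retina, stood at 46.6 ± 1.5 CPM against 6.75 ± 1.3, 9.14 ± 3.9 and 9.36 ± 1.9. Genes of the cortical layers did not set this group apart, with a median log2 difference of -0.03 (SD 0.35 over 21 genes) from the others. Every comparison below with the control unstressed group contains these differences. With the mean of the bulb genes as a covariate, chosen after the data were seen, edgeR called 0 genes for stress on the control diet (1525 under an unadjusted p of 0.05), 0 for fructose without stress (1673), 0 for both (1654), 0 for fructose averaged (1815), 0 for the interaction (1521) and 5 for stress averaged. DESeq2 without the covariate called 1064, 1880, 2237, 2506, 112 and 1720. Of the variance of that covariate 99.26% lay between groups, so the model could not separate it from the control unstressed group. Across groups, Malat1, a nuclear noncoding RNA, was at 3758, 3412 and 3537 CPM in fructose unstressed libraries 1 and 3 and fructose stressed library 1, and at 4705 CPM or above in the other 9. These 3 libraries also lay at -25, -20.7 and -12.6 on the second principal component and the 9 others at -5.1 or above.

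**Figure D1:**
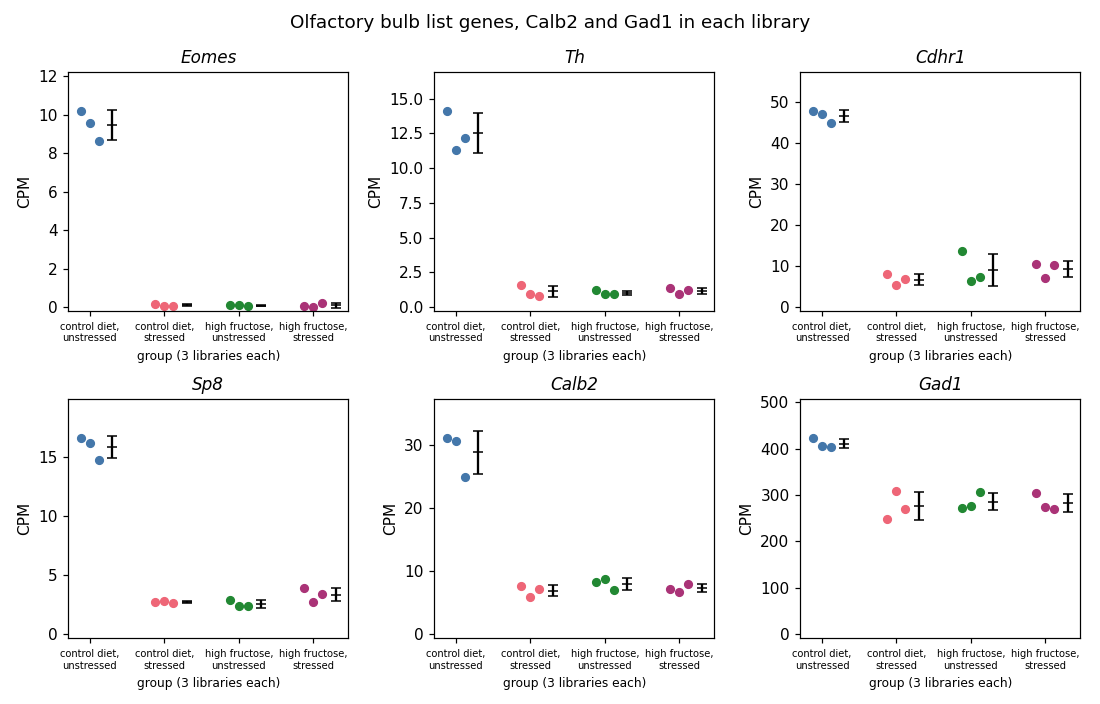
CPM (vertical axis) of Eomes, Th, Cdhr1, Sp8, Calb2 and Gad1 in each of the 12 libraries by group (horizontal axis); points are libraries and bars the mean and SD of 3. In every panel the 3 control unstressed libraries lie above the other 9, for Eomes at a mean of 9.46 CPM against 0.101 or less.

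On the control diet, stress was accompanied by lower expression of genes that glucocorticoid hormones induce. Of 24 such genes, 16 fell and none rose, and 21 fell when adjusted over the list alone. Cebpd, a transcription factor, fell from 9.26 ± 0.82 to 2.98 ± 0.46 CPM (SD, n = 3), a log2 change of -1.62 ± 0.16 (SE; adjusted p = 3.22e-06). Map3k6 fell by 1.79 ± 0.17, Cdkn1a, an inhibitor of the cell cycle, by 1.84 ± 0.16 and Errfi1, an inhibitor of EGF receptor signalling, by 0.82 ± 0.08. Fkbp5, a cochaperone that restrains the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), fell from 58.4 ± 5.5 to 20.7 ± 4.6 CPM (adjusted p = 0.00238), and Sgk1, a glucocorticoid-induced kinase, from 141 ± 15 to 75 ± 21 CPM (adjusted p = 0.0471). The receptor gene itself, Nr3c1, rose by 0.38 ± 0.08 on the log2 scale, against 0.11 ± 0.08 on high fructose (adjusted p = 0.569; interaction -0.27 ± 0.11, adjusted p = 0.607), and it also differed between the unstressed groups. The list was lower than other genes also with an estimated correlation (adjusted p = 0.0134).

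Members of several further groups changed with stress on the control diet, some in opposite directions. Of 24 genes of the cholesterol list, 14 rose and none fell, and 19 rose when adjusted over the list alone. Cyp51 rose by 0.43 ± 0.06 on the log2 scale and Insig1, a sterol-regulated protein of the endoplasmic reticulum, by 0.42 ± 0.07. The call of that list was lost with an estimated correlation (adjusted p = 0.105 with an estimated correlation). Some of these genes were also higher in fructose unstressed than in control unstressed libraries, as given below. Of 21 microglial genes 6 rose, among them Cx3cr1 (0.52 ± 0.07), Gpr34 (0.69 ± 0.12) and Siglech (0.58 ± 0.09), and Sall1 fell by 0.28 ± 0.06. Adjusted over the list alone, 6 rose and 2 fell (adjusted p = 0.641 with an estimated correlation). Among 15 endothelial genes, the transporter Slco1a4 (0.82 ± 0.09) and the angiopoietin receptor Tek (0.67 ± 0.08) rose, while the glucose transporter Slc2a1 (-0.96 ± 0.1) and the lipid transporter Mfsd2a (-0.68 ± 0.09) fell. Adjusted over the list alone 5 rose and 4 fell, with a median log2 change of -0.08 and a mean of 0. Of 27 immediate early genes, Npas4, an activity-induced transcription factor, rose from 7.42 ± 1.2 to 22.1 ± 6.8 CPM and Maff fell from 5.98 ± 1 to 1.57 ± 0.19. Adjusted over the list alone 2 were higher and 1 lower. Fos (log2 0.59 ± 0.38, adjusted p = 0.468) and Arc (0.66 ± 0.42, adjusted p = 0.473) did not pass. Of the genes outside the lists, Tnfsf10 (1.85 ± 0.21), Sox13 (0.81 ± 0.09) and St8sia4, a polysialic acid synthase (0.71 ± 0.07), rose, as did Hes5, a target of Notch (1.09 ± 0.16).

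Among the largest falls with stress on the control diet were those of bulb genes, which were high in the control unstressed libraries. Of 10 genes of the olfactory bulb list 9 fell, and 10 when adjusted over the list alone, with Eomes 93.2-fold, Th 11.3-fold, Cdhr1 6.94-fold and Sp8 5.85-fold lower. Beside them 9 of 17 interneuron genes fell, 10 when adjusted over the list alone. Of the same list Pvalb (-0.16 ± 0.19, adjusted p = 0.73) and Npy (-0.07 ± 0.18, adjusted p = 0.897) did not pass. For stress on high fructose none of the 17 passed, with 1 higher when adjusted over the list alone. Calb2 fell by 2.07 ± 0.11, Dlx1 by 0.59 ± 0.06, Dlx2 by 1.03 ± 0.12 and Gad1, which makes GABA, by 0.57 ± 0.07 on the log2 scale. Both lists kept their call with an estimated correlation (adjusted p = 1.91e-05 and 0.0013). Of 6 tested ependymal genes only Dnah11 fell (-4.66 ± 0.28), also when adjusted over the list alone, and its list was called with an estimated correlation too (adjusted p = 0.023). In all, 1135 of 22460 genes passed, 412 higher and 723 lower, with a median fold of 1.38. The count was 649 without control unstressed library 1, 627 without control unstressed library 2, 722 without control stressed library 1 and 721 without control stressed library 3. It was 1707 with only the 6 libraries of this diet in the model.

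**Figure D2:**
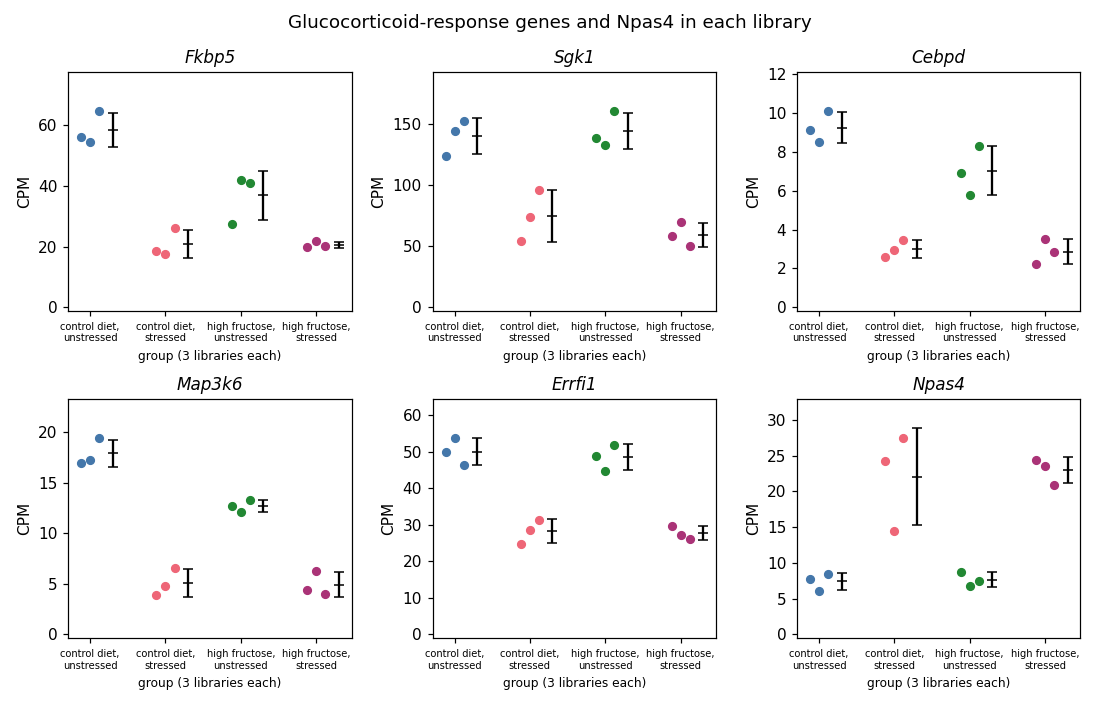
CPM (vertical axis) of Fkbp5, Sgk1, Cebpd, Map3k6, Errfi1 and Npas4 in each library by group (horizontal axis); points are libraries and bars the mean and SD of 3. Means of Cebpd are 9.26 and 7.02 CPM in the unstressed groups and 2.98 and 2.86 CPM in the stressed groups, and those of Npas4 are 7.42 and 7.66 against 22.1 and 23 CPM.

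On the high fructose diet, where no control unstressed library entered the comparison, stress again went with lower glucocorticoid-induced genes. Of the 24 genes 10 fell and none rose, and 17 fell when adjusted over the list alone. Cebpd fell from 7.02 ± 1.3 to 2.86 ± 0.64 CPM (SD, n = 3; log2 -1.29 ± 0.16, adjusted p = 0.000347), Errfi1 by 0.81 ± 0.08, Map3k6 by 1.37 ± 0.17, Klf15 by 0.65 ± 0.1, Nfkbia, the inhibitor of NF-kappaB, by 1.37 ± 0.22 and Sgk1 by 1.28 ± 0.21 on the log2 scale. Fkbp5 (-0.84 ± 0.19, adjusted p = 0.0813) and Tsc22d3 (-1.05 ± 0.21, adjusted p = 0.0545) did not pass, and their interaction values are given below. The list's call was lost with an estimated correlation (adjusted p = 0.0727 with an estimated correlation). Outside it, Txnip, an inhibitor of glucose uptake, fell from 27.1 ± 4 to 13.2 ± 0.73 CPM, the mitochondrial uncoupling protein gene Ucp2 from 28.5 ± 1.3 to 14.4 ± 1.8 and Maff from 5.72 ± 1.6 to 1.36 ± 0.4.

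Npas4 rose on this diet too, from 7.66 ± 1 to 23 ± 1.8 CPM (log2 1.58 ± 0.23, adjusted p = 0.0127), as did Hes5 (1.33 ± 0.16), Mycn (1.09 ± 0.12), St8sia4 (0.6 ± 0.07), Mex3b (0.62 ± 0.08) and Map3k1 (0.49 ± 0.08). Among endothelial genes Slco1a4 (0.58 ± 0.09) and Tek (0.35 ± 0.08) rose and Slc2a1 (-0.68 ± 0.1) and Mfsd2a (-0.52 ± 0.09) fell, with 3 higher and 3 lower when adjusted over the list alone. Of 16 circadian clock genes, Ciart, a repressor of the clock, fell from 28.2 ± 2.7 to 16.2 ± 1.1 CPM (adjusted p = 4.33e-05), and 4 fell when adjusted over the list alone (adjusted p = 0.62 with an estimated correlation). Of 13 mitochondrially encoded genes mt-Nd3 fell by 0.99 ± 0.17, alone also when adjusted over the list alone (adjusted p = 0.79 with an estimated correlation). Of the cholesterol list none of 24 passed, also adjusted over the list alone, with a median log2 change of 0.07. Of 10 bulb genes none passed, and the median log2 change of that list was 0.16. In all 337 genes passed, 153 higher and 184 lower, with a median fold of 1.49. The count was 199 without fructose unstressed library 1, 144 without fructose unstressed library 3, 183 without fructose stressed library 2 and 137 without fructose stressed library 3. It was 171 with only the 6 libraries of this diet in the model and 125 with the description number as a block. The split of these 6 that set fructose unstressed libraries 1 and 3 and fructose stressed library 1, those low in Malat1, against the rest called 711. Without those 3 libraries, a setting chosen after the data were seen that leaves 1 fructose unstressed library, 50 passed.

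The effects of stress on the 2 diets, measured in separate libraries, went the same way for most called genes. Of the genes called on both diets, 74 rose on both where independent lists would share 2.81 (two-sided Fisher's exact test, p = 6.8e-88), and 111 fell on both where 5.92 would be shared (p = 1.53e-118), while 2 went in opposite directions. These p-values treat genes as independent, which they are not. Across 16626 genes of at least 1 CPM, Pearson's r of the log2 changes was 0.417, a correlation across genes and not across samples. Shared falls included Cebpd, Errfi1, Map3k6, Klf9, Klf15, Arrdc2, Maff, Txnip and Slc2a1, and shared rises Npas4, Hes5, St8sia4, Adrb1, Sox9, Slco1a4 and Tek.

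**Figure D3:**
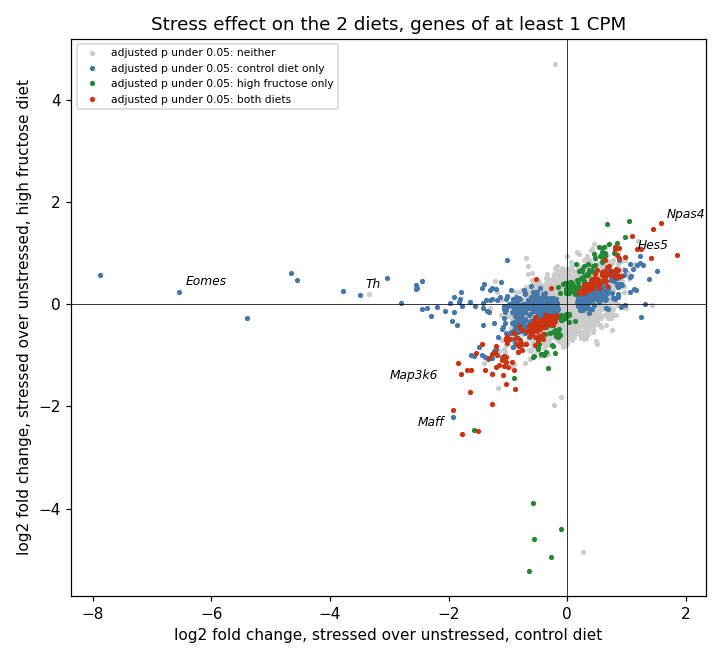
Each point is a gene of at least 1 CPM, with its log2 fold change for stress on the control diet (horizontal axis) against that on the high fructose diet (vertical axis), coloured by the diets on which it passed an adjusted p of 0.05. Of all tested genes 74 were called higher and 111 lower on both diets, and those plotted lie at the upper right and lower left. The same colour holds any plotted gene of the 2 called in opposite directions. Eomes and Th lie far to the left and near 0 on the vertical axis.

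In unstressed mice, high fructose was accompanied by small rises of neuronal signalling genes beside the large falls of bulb genes. Some of the rises were larger in fructose unstressed libraries 1 and 3, which were low in Malat1 (3758 and 3412 CPM, against 4705 in library 2). Gabrb2 stood at 283 and 269 CPM in them and at 248 in library 2, Tpi1 at 364 and 346 against 319, and Sv2b at 749 and 646 against 608. Of 19 genes of GABA signalling 8 rose, all receptor subunits, and 11 when adjusted over the list alone. Gabrb2 rose from 224 ± 6.5 to 267 ± 17 CPM (SD, n = 3; log2 0.25 ± 0.06, adjusted p = 0.0122), Gabrb1 by 0.28 ± 0.06 and Gabra3 by 0.28 ± 0.06, while Gad1 fell by 0.52 ± 0.07. Gabra4 and Gabrb1 overlap each other on opposite strands, so the 2 are not separate evidence. Of 22 glutamate receptor genes 5 rose and Grm4 fell, with 8 higher and 3 lower when adjusted over the list alone. Grm3 rose by 0.28 ± 0.05 and Grm5 by 0.3 ± 0.07. Of 21 genes of vesicle release 4 rose, Sv2b by 0.35 ± 0.07, Stx1a by 0.2 ± 0.05, Syt1 by 0.2 ± 0.05 and Slc17a7 by 0.2 ± 0.05, and 8 when adjusted over the list alone. Of 22 genes of glycolysis and monosaccharide transport 5 rose, among them Slc16a7, a carrier of lactate and pyruvate (0.35 ± 0.06), Tpi1 (0.23 ± 0.06) and Ldha (0.22 ± 0.06), and 13 rose and 1 fell when adjusted over the list alone. The calls of the GABA, vesicle and glycolysis lists were lost, each with adjusted p = 0.775 with an estimated correlation, and that of the glutamate list with adjusted p = 0.805 with an estimated correlation. Bdnf, a neurotrophin, rose by 0.42 ± 0.11, Cx3cr1 by 0.37 ± 0.07 and Nr3c1 by 0.35 ± 0.08. Of the cholesterol list 4 of 24 rose, and 14 when adjusted over the list alone (adjusted p = 0.775 with an estimated correlation). The rises with the smallest p-values included those of Rasgef1b (0.42 ± 0.06), Uhmk1 (0.31 ± 0.05) and Rab27b (0.4 ± 0.06).

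Genes that handle fructose did not pass in unstressed mice. Of 12 such genes none passed, also adjusted over the list alone. The fructose transporter gene Slc2a5 stood at 4.81 ± 0.44 CPM on the control diet and 5.32 ± 0.72 on high fructose (log2 0.15 ± 0.14, adjusted p = 0.546). Khk, which phosphorylates fructose, stood at 4.45 ± 0.4 and 4.21 ± 0.48 (adjusted p = 0.759). Of the glucocorticoid-induced genes 3 of 24 fell, Cdkn1a, Angptl4 and Mt1, and 11 when adjusted over the list alone (adjusted p = 0.775 with an estimated correlation). Sgk1 had a log2 change of 0.04 ± 0.2 and Fkbp5 of -0.66 ± 0.18 (adjusted p = 0.0681). Of the bulb list all 10 genes fell, also adjusted over the list alone, and of the interneuron list 9 of 17 fell, with 1 higher and 9 lower when adjusted over the list alone. Eomes was 109-fold, Th 11.9-fold and Sp8 6.11-fold lower, Calb2 fell by 1.85 ± 0.11 and Dlx1 by 0.6 ± 0.06. Both lists kept their call with an estimated correlation (adjusted p = 1.45e-05 and 0.00479). In all 1391 genes passed, 742 higher and 649 lower, with a median fold of 1.23, and 616 with the description number as a block. The count was 535, 717 and 350 without control unstressed library 1, 2 and 3, 355 without fructose unstressed library 1, 650 without fructose unstressed library 3 and 3021 without fructose unstressed library 2. Without the 3 libraries low in Malat1, a setting chosen after the data were seen, it was 131, 7 higher and 124 lower, with the single fructose unstressed library left assumed to vary like the other groups.

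In stressed mice, high fructose was accompanied by a fall of predicted genes that resemble satellite repeats and of Ciart. All 8 called genes were lower: Gm10800, Gm21738, Gm10717, Gm10718, Gm10719, Gm10722, Gm11168 and Ciart. Gm10800 (ENSMUSG00000075014, chromosome 2, 98666547 to 98667301) fell from 206 ± 86 to 6.96 ± 2.6 CPM (SD, n = 3; log2 -4.89 ± 0.41, adjusted p = 0.0134), and Gm21738 on chromosome 14 by 4.24 ± 0.47. The other 5 lie on chromosome 9 between 3000922 and 3033289, and Gm10718 had 0 counts in all 3 fructose stressed libraries and 11 to 41 in each other library. Transcripts of the 7 shared 44.2% to 87.9% of their 16-base words with one another, so their counts are uncertain between the copies. Ciart fell from 22.1 ± 0.98 to 16.2 ± 1.1 CPM (log2 -0.45 ± 0.08, adjusted p = 0.0458).

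Of the 18 genes of prior interest none passed in stressed mice on high fructose, with Txnip at log2 -0.32 ± 0.12 (adjusted p = 0.366), Slc2a5 at 0.1 ± 0.13 (adjusted p = 0.793), Khk at 0.15 ± 0.13 (adjusted p = 0.653) and Fkbp5 at -0.01 ± 0.2 (adjusted p = 0.987). Among the other genes nearest to a call, Etv1, a transcription factor of deep cortical layers, had a log2 change of 0.29 ± 0.06 (adjusted p = 0.117) and Ptchd1 of 0.39 ± 0.08 (adjusted p = 0.163). At the preset correlation 16 lists were called, among them GABA signalling with a median log2 change of 0.1, and none of the 16 kept its call (adjusted p = 0.86 with an estimated correlation for each). edgeR called 8 genes, 2572 were under an unadjusted p of 0.05, and DESeq2 called 20. With no filter on low counts 237 passed, 69 higher and 168 lower. The count was 1 without fructose stressed library 1 or 3 and 0 without fructose stressed library 2, where 3410 genes were under an unadjusted p of 0.05. It was 4 without control unstressed library 1 or 3, and 5 without control unstressed library 2, control stressed library 3 or fructose unstressed library 1 or 3. With only the 6 libraries compared in the model edgeR called 0 (2374 under an unadjusted p of 0.05), with the description number as a block 0 (1867), and with 1 surrogate variable 1. Without the 3 libraries low in Malat1 it called 1.

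**Figure D4:**
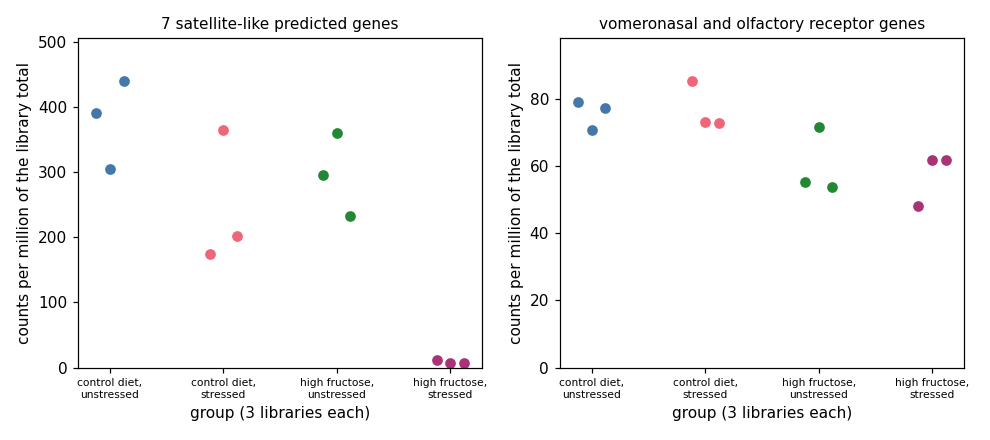
Counts scaled to the library total, as CPM (vertical axes), of 7 satellite-like predicted genes (left) and of 1972 vomeronasal and olfactory receptor genes (right) in each library, by group (horizontal axis). The 3 fructose stressed libraries hold 6.6 to 12.2 CPM of the satellite-like genes against 174 to 440 in the other 9, and 48.1 to 61.6 CPM of the receptor genes against 53.6 to 85.3.

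Between mice with both high fructose and stress and mice with neither, most glucocorticoid-induced genes differed. Of the 24 genes 19 fell, and 21 when adjusted over the list alone, among them Cebpd (-1.69 ± 0.16), Map3k6 (-1.86 ± 0.17), Cdkn1a (-1.92 ± 0.16), Fkbp5 (-1.5 ± 0.19), Sgk1 (-1.24 ± 0.21) and Hif3a (-1.83 ± 0.34). The list kept its call with an estimated correlation (adjusted p = 0.0243). Of the cholesterol list 12 of 24 rose, and 16 when adjusted over the list alone, with Insig1 at 0.39 ± 0.07 (adjusted p = 0.386 with an estimated correlation). Of the fructose list Txnip fell by 1.34 ± 0.12 and Glyctk, glycerate kinase, rose by 0.67 ± 0.18. Of the microglial list 6 rose, among them Cx3cr1 (0.62 ± 0.07), and 2 fell, and the same numbers passed when adjusted over the list alone. Bdnf (0.53 ± 0.11), Adcyap1, the precursor of the neuropeptide PACAP (0.69 ± 0.14), Htr1a (0.38 ± 0.07) and Adrb1 (0.75 ± 0.07) rose, and Acan, the core protein of perineuronal nets, fell by 0.87 ± 0.15. All 10 bulb genes fell, also adjusted over the list alone, with Eomes 92.5-fold lower, as did 9 of 17 interneuron genes, 10 when adjusted over the list alone, with Calb2 at -1.98 ± 0.11. Both kept their call with an estimated correlation (adjusted p = 4.77e-05 and 0.00931). In all 2350 genes passed, 1101 higher and 1249 lower, with a median fold of 1.33, and 1523 with the description number as a block. The count was 1391, 1430 and 1515 without control unstressed library 1, 2 and 3, 1519 without fructose stressed library 1 and 1533 without fructose stressed library 3.

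Averaged over the diets, stress went with lower glucocorticoid-induced genes. Of these 18 of 24 fell, 21 when adjusted over the list alone, with Cebpd at -1.46 ± 0.12, Errfi1 at -0.81 ± 0.06, Fkbp5 at -1.16 ± 0.13, Tsc22d3 at -1.15 ± 0.15 and Sgk1 at -1.09 ± 0.15. The list kept its call with an estimated correlation (adjusted p = 0.00821). Of the cholesterol list 14 of 24 rose, 18 when adjusted over the list alone, with Insig1 at 0.31 ± 0.05 and Cyp51 at 0.27 ± 0.04 (adjusted p = 0.315 with an estimated correlation). On high fructose alone none of these 24 passed, with a median log2 change of 0.07. In the interaction 15 were lower when adjusted over the list alone. Without stress, 4 of 24 were also higher on high fructose than on the control diet, 14 when adjusted over the list alone. Between the stressed groups none passed, with a median log2 change of -0.07. The averaged rise thus came mainly from lower values in the control unstressed libraries. Of 15 endothelial genes Slco1a4 (0.7 ± 0.06), Tek (0.51 ± 0.06), Cldn5 and Itm2a rose and Slc2a1 (-0.82 ± 0.07), Mfsd2a (-0.6 ± 0.07) and Adgrl4 fell. The same 4 and 3 passed when adjusted over the list alone, with a median log2 change of -0.03 and a mean of 0.03. Npas4 (1.58 ± 0.16), Hes5 (1.21 ± 0.11), Mycn (0.95 ± 0.09) and the toll-like receptor gene Tlr2 (1.12 ± 0.2) rose, and Maff (-2 ± 0.16), Apold1 (-2.07 ± 0.31) and B4galt1 (-0.87 ± 0.07) fell. Of the bulb genes 8 of 10 fell, and 9 when adjusted over the list alone, with Sp8 at -1.08 ± 0.09, since the unstressed arm holds the control unstressed libraries. In all 2013 genes passed, 905 higher and 1108 lower, with a median fold of 1.26, and 1316 without control unstressed library 1. Without the 3 libraries low in Malat1 1110 passed.

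Averaged over stress, high fructose went with changes of small size, and some of the genes that rose were higher in the 3 libraries low in Malat1. In fructose unstressed libraries 1 and 3 and fructose stressed library 1 Aldoa stood at 1060, 985 and 997 CPM and in the other fructose libraries at 940, 907 and 904, and Gabrb2 at 283, 269 and 274 against 248, 245 and 263. Without these 3 libraries 101 genes passed, 20 higher and 81 lower. Of 22 genes of glycolysis and monosaccharide transport 8 rose, among them Slc16a7 (0.21 ± 0.04), Aldoa (0.16 ± 0.04) and Ldha (0.16 ± 0.04), and 15 rose and 1 fell when adjusted over the list alone. Of the GABA list 7 of 19 rose, 11 when adjusted over the list alone, with Gabrb2 at 0.19 ± 0.04, and Gad1 fell by 0.25 ± 0.05. Both calls were lost, each with adjusted p = 0.681 with an estimated correlation. Of 22 genes of the unfolded protein response 4 rose, 7 when adjusted over the list alone, among them Hspa5, the chaperone of the endoplasmic reticulum (0.15 ± 0.04), and Pdia4 (0.21 ± 0.05), also with adjusted p = 0.681 with an estimated correlation. Ptchd1 (0.4 ± 0.06), Scn2a, a neuronal sodium channel (0.25 ± 0.04), and Adrb1 (0.26 ± 0.05) rose and Txnip fell by 0.31 ± 0.08. All 10 bulb genes fell, also adjusted over the list alone, with Sp8 at -1.15 ± 0.09, and 7 of 17 interneuron genes fell, with 1 higher and 7 lower when adjusted over the list alone. Between the stressed groups no gene of either list passed, with median log2 changes of -0.19 and 0.03, and 1 bulb gene was lower when adjusted over the list alone. Gad1, of the interneuron list, had an interaction of 0.56 ± 0.1. The falls of Gad1 and of these lists thus came mainly from the control unstressed libraries. The bulb list kept its call with an estimated correlation (adjusted p = 0.000442), and that of the interneuron list was lost (adjusted p = 0.123 with an estimated correlation). In all 2072 genes passed, 1103 higher and 969 lower, with a median fold of 1.16, and 888 with the description number as a block. The count was 1198, 1199 and 1024 without control unstressed library 1, 2 and 3, 1232 and 1155 without control stressed library 1 and 3, 1016, 4075 and 1080 without fructose unstressed library 1, 2 and 3, and 1056 without fructose stressed library 1.

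The effect of stress differed between the diets for genes high in the control unstressed libraries. A positive interaction means a higher stress effect on high fructose than on the control diet, and 7 of 10 bulb genes had one, 9 when adjusted over the list alone. Among them were Th at 3.67 ± 0.31, Sp8 at 2.93 ± 0.19 and Eomes at 6.77 ± 1 on the log2 scale. So had 7 of 17 interneuron genes, 9 when adjusted over the list alone, with Calb2 at 1.94 ± 0.16 and Gad1 at 0.56 ± 0.1, and both lists kept their call with an estimated correlation (adjusted p = 3.53e-05 and 0.00111). Of 13 negative interactions, those named here were of Ciart (-0.55 ± 0.11), Lct, the lactase gene (-1.5 ± 0.32), Dclk3 (-0.45 ± 0.1) and Atad2 (-0.54 ± 0.12). No glucocorticoid-induced gene of 24 passed, also adjusted over the list alone, with Fkbp5 at 0.65 ± 0.27 (adjusted p = 0.652) and Tsc22d3 at 0.21 ± 0.29 (adjusted p = 0.939). At the preset correlation that list was higher (median 0.27, adjusted p = 0.000145), a call that was lost (adjusted p = 0.963 with an estimated correlation). No cholesterol gene of 24 passed, 15 being lower when adjusted over the list alone, and the list was lower at the preset correlation (median -0.27, adjusted p = 2.82e-14), a call that was lost (adjusted p = 0.278 with an estimated correlation). In all 98 genes passed, 85 higher and 13 lower, with a median fold of 2.45, 51 with the description number as a block and 60 without the 3 libraries low in Malat1.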

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

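The genes of this paragraph were singled out because the effect of stress differed between the diets in a test of that difference, the interaction. Of the patterns weighed after it, only the bulb genes are among the genes named here. For this comparison the rule for named genes left out predicted-gene names. The satellite-like genes, low in the fructose stressed libraries alone, could therefore not be among them. The tests of the cortical layers, of the variance of the bulb genes, of the high fructose diet alone, of the receptor and satellite-like genes and of the splits were chosen after the result was seen, and those of the second lists and of the clock genes before. In all 98 genes differed, 85 with a positive and 13 with a negative value, of which those taken by the rule for named genes follow. Positive values among them, for a stress effect higher on high fructose, were those of Sp8 (2.93), Lgr5 (2.14), Cacng5 (1.76), Pbx3 (2), Gng4 (1.34), Calb2 (1.94), Th (3.67), Frmd7 (5.03), Doc2g (2.84), Sp7 (3.56), Dlx6os1 (0.8), Vipr2 (4.04), Dnah11 (5.26), Dlx1 (0.69), Zic1 (0.96), Shisa3 (2.05), Dlx5 (1.57), Eomes (6.77), Sall1 (0.58), Dlx2 (1.13), Gad1 (0.56), Dlx6 (1.19), Omp (2.9), Adamts19 (5.12), Ms4a15 (8.45), Cdhr1 (2.82) and Aqp1 (2.63). Negative values among them were those of Ciart (-0.55), Dclk3 (-0.45), Lct (-1.5) and Atad2 (-0.54), all on the log2 scale. Of 100 splits of the samples 10 gave as many as 98 genes, the real one included, and the highest other gave 2013. Of the 9 others 7 kept the 2 control diet groups whole and so held the real stress effect of that diet, and 2 set the 3 libraries low in Malat1 against the other fructose libraries, which points to a structure of the samples. These splits therefore leave open whether chance gave the 98.

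The bulb genes were higher in all 3 control unstressed libraries than in the 9 others, but that these libraries were wholly of another tissue was argued against by 21 genes of the cortical layers, whose median log2 difference was -0.03 (SD 0.35). A candidate explanation is olfactory bulb tissue dissected along with the cortex in these libraries. Of 16 further bulb genes written down, 13 were tested and 6 had all 3 control unstressed libraries above the others, with a median log2 difference of 0.46. Dcx stood at 59.9 against 43.7 CPM and Ntng1 at 22.9 against 15.5 CPM. If all libraries were alike, chance would give this order in 0.455% of genes. These libraries stood apart over many genes, and the share over all tested genes was not counted, so the 6 cannot be weighed against chance. The 6 of 13 were under the 0.5 of genes set in advance, and 12 of the 13 were also above 1 CPM in the others. A change inside the cortex cannot be told apart from it, since 99.26% of the variance of the bulb genes lay between groups and no label gives the dissection.

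Of 24 glucocorticoid-induced genes 16 were lower with stress on the control diet and 10 on high fructose, where the list's call was lost (adjusted p = 0.0727 with an estimated correlation). Bulb tissue in the control unstressed libraries was argued against by the high fructose diet, where no such library entered and the median log2 change was -0.73. Another time of day at collection was argued against by clock genes of opposite phase, whose difference between stressed and unstressed libraries was -0.06 ± 0.07 (SE), although of other clock genes Ciart (-0.53), Per1 (-0.42), itself glucocorticoid-induced, and Bhlhe41 (-0.15) fell with stress averaged over diets. Lower glucocorticoid signalling in the stressed libraries may account for it: of 12 further glucocorticoid-induced genes 8 were lower on both diets at an unadjusted p under 0.05, among them Bcl6, Tiparp, Gadd45g, Crispld2 and Gpd1, and all 12 had negative values on both. The further genes were measured in the same libraries as the first list, and the share of all tested genes lower on both diets was not counted. Lower glucocorticoid signalling remains a hypothesis, since no hormone was measured and the time from stress to collection was not given in the sources used here.

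The 7 satellite-like predicted genes were lower in all 3 fructose stressed libraries than in the 9 others, with a log2 ratio of -5.12. Less genomic DNA carried into these libraries was weighed on 1972 vomeronasal and olfactory receptor genes, hardly transcribed in cortex, whose log2 ratio was -0.31. That small fall argues against it only if most of their counts came from genomic DNA, which was not shown. The receptor genes were also low in fructose unstressed libraries 1 and 3, at 55.2 and 53.6 CPM, where the satellite-like genes stood at 296 and 233 CPM. Transcripts of the 7 satellite-like genes resemble themselves when shifted by 234 bases, close to the repeat length of mouse major satellite, with matches of 62.4% to 65.2% in 5 of them, of 62.9% at 237 bases in Gm11168 and of 56.3% at 225 bases in Gm10800. Satellite transcription changed by diet and stress together may account for it. It stays open, since it was tested only on the genes that showed it; the labels name no batch, and the libraries low in Malat1 were spread over this group and the fructose unstressed group.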

How the results depend on the processing

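Of the settings below the covariate of bulb genes and the omission of the 3 libraries low in Malat1 were chosen after the result was seen. Of 856 values of named genes 734 passed, and 292 of these no longer passed without some library. Except under the bulb covariate, no value that passed in the main model or in the other setting turned direction. Values that passed in neither were not compared for direction. With DESeq2 798 of 848 kept their side of the threshold, with RLE 836 of 856, with 1 surrogate variable 787 and with no filter 823. With the title number as a block 795 did, with the description number 662 and with only the groups compared 468 of 510. DESeq2 gave no p-value for the values of the 856 that are missing from its 848. Where a count changed, the cause was not tested unless given. With 25.1 to 36.1 M fragments per library and 3 libraries per group, the test recovered 74 of 100 simulated changes of 1.5-fold, so smaller changes can be missed.

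Without each library in turn, counts ran from 627 to 1321 for stress on the control diet, 137 to 452 for stress on high fructose, 350 to 3021 for fructose without stress, 0 to 10 for fructose with stress (0, with 3410 under an unadjusted p of 0.05, without fructose stressed library 2), 1391 to 2908 for both together, 1316 to 2260 for stress averaged, 1016 to 4075 for fructose averaged and 68 to 93 for the interaction. The highest of fructose without stress, both together and fructose averaged, and 452, were without fructose unstressed library 2. Called lists ran from 9 to 12, 8 to 17, 9 to 17, 9 to 19, 6 to 9, 8 to 17, 12 to 23 and 7 to 14, in that order, against 10, 8, 11, 16, 6, 17, 18 and 7 with all libraries. With an estimated correlation 4, 0, 3, 0, 3, 3, 1 and 2 lists were called.

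With no filter on low counts, where more genes are tested, 1786 passed for stress on the control diet, 793 for stress on high fructose, 2524 for fructose without stress, 237 for fructose with stress, 3429 for fructose averaged and 259 for the interaction. With only the groups compared, 1707 passed for stress on the control diet, 171 for stress on high fructose and 0 for fructose with stress (2374 under an unadjusted p of 0.05). Without fructose unstressed libraries 1 and 3 and fructose stressed library 1, those low in Malat1, which leaves 1 fructose unstressed library assumed to vary like the other groups, 1687 passed for stress on the control diet, 50 for stress on high fructose, 131 for fructose without stress, 1 for fructose with stress, 1972 for both together, 1110 for stress averaged, 101 for fructose averaged and 60 for the interaction. For fructose with stress DESeq2 called 20, the bulb covariate 14 and 1 surrogate variable 1.

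The replicate numbers did not pair the libraries across groups: the mean correlation of libraries with the same title number, within-group means removed, was -0.012 over 18 pairs (-0.315 to 0.355), and with the same description number -0.029 over 13 pairs (-0.208 to 0.248). As a block the title number gave 1085, 314, 1389, 6, 2264, 1867, 2078 and 90 genes, in the order above. The description number gave 125 for stress on high fructose, 616 for fructose without stress, 0 for fructose with stress (1867 under an unadjusted p of 0.05), 1523 for both together, 888 for fructose averaged and 51 for the interaction.

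With the bulb genes as a covariate edgeR called 0 genes for stress on the control diet, fructose without stress, both together, fructose averaged and the interaction (1525, 1673, 1654, 1815 and 1521 under an unadjusted p of 0.05) and 5 for stress averaged. In this model 88 log2 changes that had passed without the covariate turned direction, none passing with it (smallest adjusted p = 0.778). Since 99.26% of the variance of the covariate lay between groups, these values are poorly determined. For stress on the control diet these were Hhex -1.13, Frmd7 0.36, Th 1.16, Tsc1 -0.1, Pou3f2 -0.13, Reln 0.61, Trh 1.59, Cacna1c 0.82, Nmb 2.88, Igf1 0.25, Col4a1 0.34, Calb2 0.44, Cdhr1 1.78, Tbx21 0.47, Adarb2 0.11, Trem2 -0.03, Nr3c1 0, Pdgfrb -0.28 and Adrb1 0. For fructose without stress these were Frmd7 0.68, Th 1.46, Pou3f2 -0.28, Reln 0.77, Trh 1.95, Nmb 2.59, Igf1 0.3, Col4a1 0.42, Dnajb1 -0.5, Calb2 0.85, Cdhr1 2.59, Tbx21 1.2, Adarb2 0.15, Nr3c1 -0.06 and Adrb1 -0.27. For both together these were Hhex -1.43, Eomes 0.02, Frmd7 1.13, Th 1.6, Ahr -0.36, Tsc1 -0.07, Synpo2 -0.58, Pou3f2 -0.19, Reln 0.79, Trh 1.85, Nmb 2.64, Igf1 0.31, Col4a1 0.36, Dnajb1 -0.53, Calb2 0.71, Cdhr1 2.58, Rplp1 0.01, Tbx21 0.05, Adarb2 0.18, Trem2 -0.15, Pdgfrb -0.35 and mt-Nd3 0.78. For stress averaged these were Tnfrsf25 -1.76, Frmd7 0.4, Calb2 0.15, Rgs5 -0.11, Atp5c1 0.01, Gad2 0.11, Atp5f1 0, Synpo2 -0.01, Pou3f2 -0.02, Reln 0.32, Trh 0.74, Cacna1c 0.4, Th 0.65, Col4a1 0.14, Cdhr1 0.89, Irf9 -0.73, Pdgfrb 0 and mt-Nd3 0.03. For fructose averaged these were Eomes 0.14, Frmd7 0.73, Th 0.95, Trh 1.1, Nmb 1.18, Col4a1 0.23, Dnajb1 -0.19, Calb2 0.56, Cdhr1 1.7, Tbx21 0.39 and Adrb1 -0.06. For the interaction these were Th -1.02, Calb2 -0.58 and Cdhr1 -1.78.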

Other observations

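The splits of the samples were counted after the results were seen. Averaged over the diets, some mitochondrially encoded, vascular, meningeal and inflammatory genes changed with stress. Of 13 mitochondrial genes 3 fell, and 10 when adjusted over the list alone, with mt-Nd3 at -0.69 ± 0.12 and mt-Nd4l at -0.74 ± 0.18 on the log2 scale (SE; adjusted p = 0.423 with an estimated correlation). Of 10 pericyte and smooth muscle genes Pdgfrb (0.32 ± 0.05), Rgs5 (0.12 ± 0.03) and Notch3 (0.17 ± 0.05) rose and the potassium channel gene Kcnj8 fell by 0.54 ± 0.12, the same genes as when adjusted over the list alone. Of 17 leptomeningeal genes the collagens Col1a1 (0.4 ± 0.11) and Col3a1 (1.08 ± 0.2) rose, also when adjusted over the list alone (adjusted p = 0.787 with an estimated correlation). Of 20 inflammatory genes Il1a (1.38 ± 0.27), Tlr2 (1.12 ± 0.2) and Nos2 (1.01 ± 0.28) rose and Nfkbia fell by 1.32 ± 0.16, with 3 higher and 2 lower when adjusted over the list alone. Of 25 genes of insulin and leptin signalling Irs2, an adaptor of the insulin receptor, fell by 0.5 ± 0.06, Pik3r1 by 0.16 ± 0.04 and Ptpn1 by 0.18 ± 0.05, and Tsc1 rose by 0.17 ± 0.03, with 1 higher and 5 lower when adjusted over the list alone (adjusted p = 0.787 with an estimated correlation).

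Averaged over stress, high fructose went with higher Fezf2 (0.27 ± 0.08), Etv1 (0.21 ± 0.04) and Crym (0.42 ± 0.11), 3 of 12 genes of the deep cortical layers, also when adjusted over the list alone (adjusted p = 0.681 with an estimated correlation). All 3 libraries low in Malat1 lie in the fructose groups, so the rises of this paragraph are not separated here from that difference between libraries. Of 30 monoamine genes the serotonin receptor genes Htr1a (0.24 ± 0.05) and Htr1b (0.39 ± 0.09) and Adrb1 rose and Th fell by 1.74 ± 0.15, with 7 higher and 1 lower when adjusted over the list alone, a median log2 change of 0.08 and a mean of -0.01 (adjusted p = 0.681 with an estimated correlation). Th is also of the bulb list and was high only in the control unstressed libraries (interaction 3.67 ± 0.31), so its fall is not a general change with fructose. Of 12 heat shock genes Hsph1, Dnajb1 and Hspa8 rose, also when adjusted over the list alone (adjusted p = 0.681 with an estimated correlation).

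Other splits of the samples were fitted in the same way. For stress averaged over diets, 1 of 100 splits, the real one, gave as many as 2013 genes and the highest other gave 558. For fructose averaged over stress, 1 of 100, the real one, gave as many as 2072 and the highest other gave 842. Random labels thus rarely gave as many in either comparison. Both hold the control unstressed libraries, which were high in bulb genes. The splits therefore do not tell an effect of stress or of fructose from that difference between libraries. For comparisons of 3 libraries with 3 the 10 splits are too few to decide. Stress on the control diet gave 1135 against 1 for the highest other, high fructose in unstressed mice 1391 against 0, high fructose in stressed mice 8 against 2, and both together 2350 against 0. Stress on high fructose gave 337, and 2 of its 10 splits gave as many, the highest other giving 711. That split sets fructose unstressed libraries 1 and 3 and fructose stressed library 1 against the rest, which points to a structure of these samples other than stress, and Malat1 was lower in those 3 libraries, at 3758, 3412 and 3537 CPM.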
